A study of Sus scrofa with 8 samples.

How the data were processed

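RNA was sequenced with paired reads on an Illumina HiSeq instrument in 8 libraries from pig (Sus scrofa). Per the labels, 4 libraries came from lymphoma clones of a lymph node tumour and 2 from lymphoma clones of the spleen, each clone grown from dissociated tumour cells and taken through 4 rounds of limiting dilution. The other libraries came from splenocytes enriched for CD21+ cells, as a normal B cell control, and for CD3+ cells, as a normal T cell control, with 1 library each. RNA came from equal numbers of cells per sample, by RNeasy column.

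The submitters' notes name Trimmomatic, Bowtie2 and edgeR without versions, and the study description gives Sscrofa11.1 as the genome. The counting tool, the annotation and the strandedness of the libraries are not given in the sources used here, so reads of a gene and of a gene overlapping it could not be separated by strand. Per the file headers, the first deposited table holds a read count per gene for 7 libraries, and the second holds the same for 8 libraries. In the second table the authors also give reads-per-million (RPM), which equalled the count over the column total within 3.6e-12. The authors' deposited p-values (raw, Bonferroni and false discovery rate, from a test with tagwise dispersions per the file headers) and their signed linear fold change, treated as a score, were read as deposited. The 7 shared libraries held identical counts in both tables. The second table ends in 2 lines with no feature ID, which hold totals and were left out.

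The tables hold 22366 features, of which 17091 had a count above 0 in some library. For 6841 features the file gives an Ensembl ID alone. A gene name table gave 877 of these a symbol, and 26 more were left as IDs because another feature already carried their symbol. Total counts ran from 16415644 to 27253505 per library, and 3 counts, the most that a count of 0 allows, came to 0.110 to 0.183 counts-per-million (CPM) of these totals. The bounds used the floors after scaling, 0.137 CPM for the CD21+ library, 0.180 for the CD3+ library and 0.0206 for the 6 clones together.

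Levels are CPM scaled by TMM factors, given for the clones as the mean ± SD of 6 libraries. Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM, filterByExpr by group, two-sided), and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 6 clones were compared as a group with the CD21+ library and, in a separate fit, with the CD3+ library, and the 4 lymph node clones were compared with the 2 spleen clones. Errors of log2 fold changes are approximate SE, the absolute log2 fold change over the square root of the F statistic of that fit. They are therefore not a measure of precision separate from the test. In the comparisons with a control, the spread came from the clones alone and the lone control library was assumed to vary like them. The labels do not say how many animals the clones came from, so p-values measure only the spread between clones.

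Where a group had no count, the fold is a lower bound from 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. Genes that sit in multi-gene families of near-identical sequence, such as the SLA genes and the ribosomal protein genes with their pseudogenes, may share reads.

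Before the data were examined, 30 gene lists were fixed: B cell identity, T cell identity, NK and cytotoxic, myeloid, erythroid and platelet, stroma and endothelium, germinal centre B, plasma cell, immunoglobulin, B cell receptor signalling, early B progenitor, proliferation, cell cycle inhibitors and p53, MYC and ribosome biogenesis, apoptosis, lymphoma oncogenes, MHC class II, MHC class I, NF-kB, homing and adhesion, costimulation and checkpoint, interferon response, cytokines and receptors, glycolysis and hypoxia, cholesterol and lipid synthesis, amino acid stress and ATF4, immediate-early and stress, telomere, mitochondrially encoded, and ribosomal protein genes. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of the comparison. The immunoglobulin list matched only 2 features and was not tested as a set. The list of ribosomal protein genes was made from symbol prefixes and so also held RPS6K kinases.

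Likeness to the controls was measured on 13040 genes that reached 1 CPM in some library, on log2(CPM + 1), by the Spearman correlation of each clone with each control. A position on the axis between the controls, +0.5 at the CD21+ library and -0.5 at the CD3+ library, was the slope of the clone's deviation on the difference between the controls. Both were tested over the 6 clones by an exact sign-flip permutation test (two-sided). The controls were compared by fold alone, with 10000 random lists matched on expression for each list.

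The named genes were set by a rule: the 10 genes of largest fitted log2 fold change in each direction (5 between sites) among those with a symbol, 10 CPM or more in the higher group and every clone on the same side, up to 4 members per list with 5 CPM or more, and a fixed set of 21 B cell, T cell and lymphoma genes. The order by fold depends on the prior count where a group had 0 counts. Of the fixed set, CR2, BCL2, MKI67 and CDKN2A matched no feature and were not analysed here. Some of the genes that the rule picked are not reported here.

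The pipeline was tested on simulated counts with a dispersion of 0.0211 and 200 changed genes. At 2-fold it recovered 89.6% of changed genes against the CD21+ control, 71.6% against the CD3+ control and 97.0% between sites, with 11, 6 and 9 false calls. At 4-fold it recovered 100% in each, and at 1.5-fold 16.4%, 13.4% and 43.3%. No unchanged set among 30 was called, but simulated genes varied independently of each other, so this does not test the preset correlation. The simulated control varied like the clones, and far fewer genes changed than passed in the data. These rates may therefore not hold for the data.

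The alternatives, whose effect is given in the closing section, were other size factors, other filters on low counts, DESeq2 1.42.0, limma-voom, all 8 libraries in a single fit, a 2-fold limit, each site alone, leaving out each clone, and the replicate number as a block between sites. Total-count scaling and the fits without lymph node clone 4 and spleen clone 2 were added after the data were seen. The alternatives for values deposited only as RPM were not needed, since counts were deposited. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Sequence reads, junctions and variants were not analysed here.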

Results

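Transcript counts were obtained for 6 cultured porcine lymphoma clones, 4 from a lymph node tumour and 2 from the spleen, and for 1 library each of CD21+ and CD3+ splenocytes. The clones held 16415644 to 27253505 counts each, the CD21+ library 25156849 and the CD3+ library 21292294. Between 14374 and 14715 features were detected per library. Transcripts of the mitochondrial genome took 7.07 ± 0.562% of counts in the clones (SD, n = 6), 10.9% in the CD21+ library and 21.6% in the CD3+ library. Ribosomal protein genes took 8.08 ± 0.282%, 10.6% and 8.61%, and the 10 most abundant genes 8.90 ± 0.700%, 13.1% and 22.3%. The control libraries have no replicates, so no SD is given for them.

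The first question the study set was whether the clones resemble B or T cells. PAX5 and EBF1, transcription factors that set B cell identity, stood at 1917 ± 222 and 372 ± 56.2 CPM in the clones, against 1011 and 73.9 in the CD21+ library and 5.16 and 0.360 in the CD3+ library. CD3E and CD8A, a chain of the T cell receptor complex and a T cell coreceptor, stood at 0.391 ± 0.131 and 0.0719 ± 0.030 CPM in the clones, against 2529.9 and 429 in the CD3+ library. Across 13040 genes the Spearman correlation with the CD21+ library was 0.815 ± 0.00590 and with the CD3+ library 0.752 ± 0.00367 (SD, n = 6). The difference of 0.0632 ± 0.00290 was above 0 in 6 of 6 clones (exact sign-flip permutation p = 0.03125, the smallest that 6 clones allow). It was 0.0341 over all genes above 0 and 0.102 over genes at 10 CPM or more, above 0 in 6 of 6 clones in both. The clones lay at 0.199 ± 0.0103 on the axis between the controls, on the CD21+ side in 6 of 6 (exact sign-flip permutation p = 0.03125). That axis held 2.97 ± 0.373% of the clones' squared deviation from the midpoint of the controls. Pairs of clones correlated at 0.982 to 0.998 and the controls with each other at 0.870, and genes are not independent replicates in any of these correlations. All 6 clones were set against the same lone library of each control, so their signs are not independent. The permutation p therefore adds little to the comparison of a single clone.

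**Figure D1:**
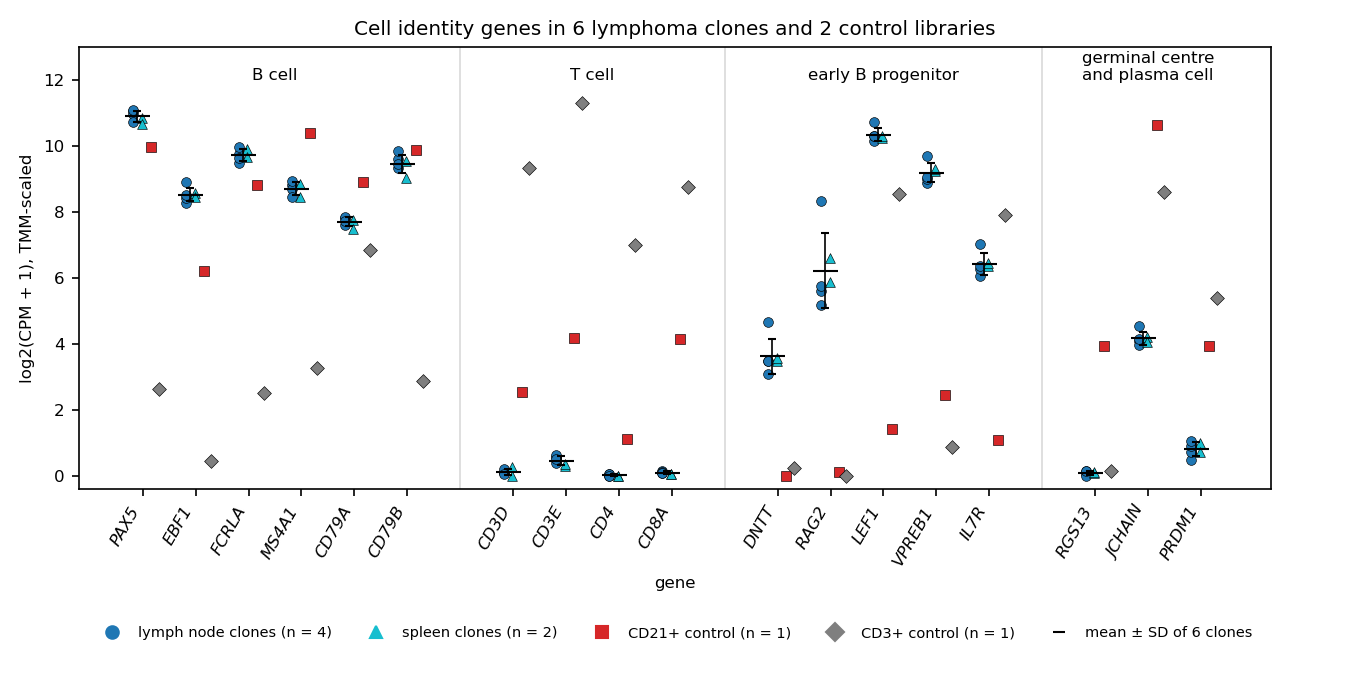
Levels of B cell, T cell, early B progenitor, germinal centre and plasma cell genes, as log2(CPM + 1) on the vertical axis, with a point per library and the mean ± SD of the 6 clones. The clones hold PAX5 at 1917 ± 222 CPM and CD3E at 0.391 ± 0.131 CPM.

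The controls were compared by fold alone, to show what the enrichments differ in. The B cell identity list had a median log2 ratio of 6.18, CD21+ over CD3+, above all 10000 random lists, and the T cell identity list one of -6.10, below all of them. Of 11529 genes at 1 CPM or more, 493 were 4-fold or more higher in the CD21+ library and 741 in the CD3+ library. Of 13 NK and cytotoxic genes, 12 were 2-fold or more higher in the CD3+ library. Of 17 myeloid genes, 9 were 2-fold or more higher in the CD21+ library.

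The comparison with CD21+ splenocytes asks which genes differ between the lymphoma clones and normal B cells. Every clone was cultured and no control was, so culture cannot be told apart from the lymphoma in any difference from a control. NUTM1, a gene whose expression is normally limited to the testis, reached 67.1 ± 5.17 CPM in the clones and had 0 counts in the CD21+ library, at least 489-fold higher (edgeR adjusted p = 1.35e-07). LEF1, a transcription factor of lymphoid progenitors, stood at 1309.8 ± 202 against 1.69 CPM, a log2 fold change of 9.59 ± 0.38 (SE, adjusted p = 4.16e-07). KLF4, a transcription factor that restrains B cell division, had 2 counts over the 6 clones against 1843 in the CD21+ library, a ratio of 6147 (95% counting interval 1699 to 50798). S1PR1, a receptor that guides lymphocytes out of lymph nodes, fell, with a log2 fold change of -7.94 ± 0.25 (adjusted p = 1.60e-07). Of 13498 genes tested, 9069 passed, 4697 higher and 4372 lower in the clones, and 5298 of these differed 2-fold or more. Under total-count scaling the median log2 fold change of all genes moved from 0.05 to 0.35, and 6190 of 9283 genes passing were higher.

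NUTM1, KCNJ16, EVC, ELOVL2, MEIS1, UCHL1, TRHDE, PPP1R3G, HOXA7 and FABP6 had the highest fitted log2 fold changes of the genes eligible to be named. All 10 had 0 counts in the CD21+ library, where the fitted value depends on the prior count, so their bounds do not rank all of them above genes such as LEF1. KCNJ16, a potassium channel subunit, stood at 145 ± 23.0 CPM, at least 1056-fold higher. MEIS1 and HOXA7, homeobox genes active in blood progenitors, stood at 76.5 ± 26.4 and 29.7 ± 2.14 CPM, at least 557-fold and 217-fold higher. The lowest bound of the 10 was that of FABP6, at least 214-fold. NUTM1 lies on chromosome 7 at 80149764 to 80159497 and shares 5277 bases with LPCAT4, which stood at 42.1 ± 3.46 CPM in the clones and 38.5 in the CD21+ library. HOXA7 lies on chromosome 18 at 45417137 to 45419113. Strandedness is not stated, so reads of overlapping genes could not be separated.

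**Figure D2:**
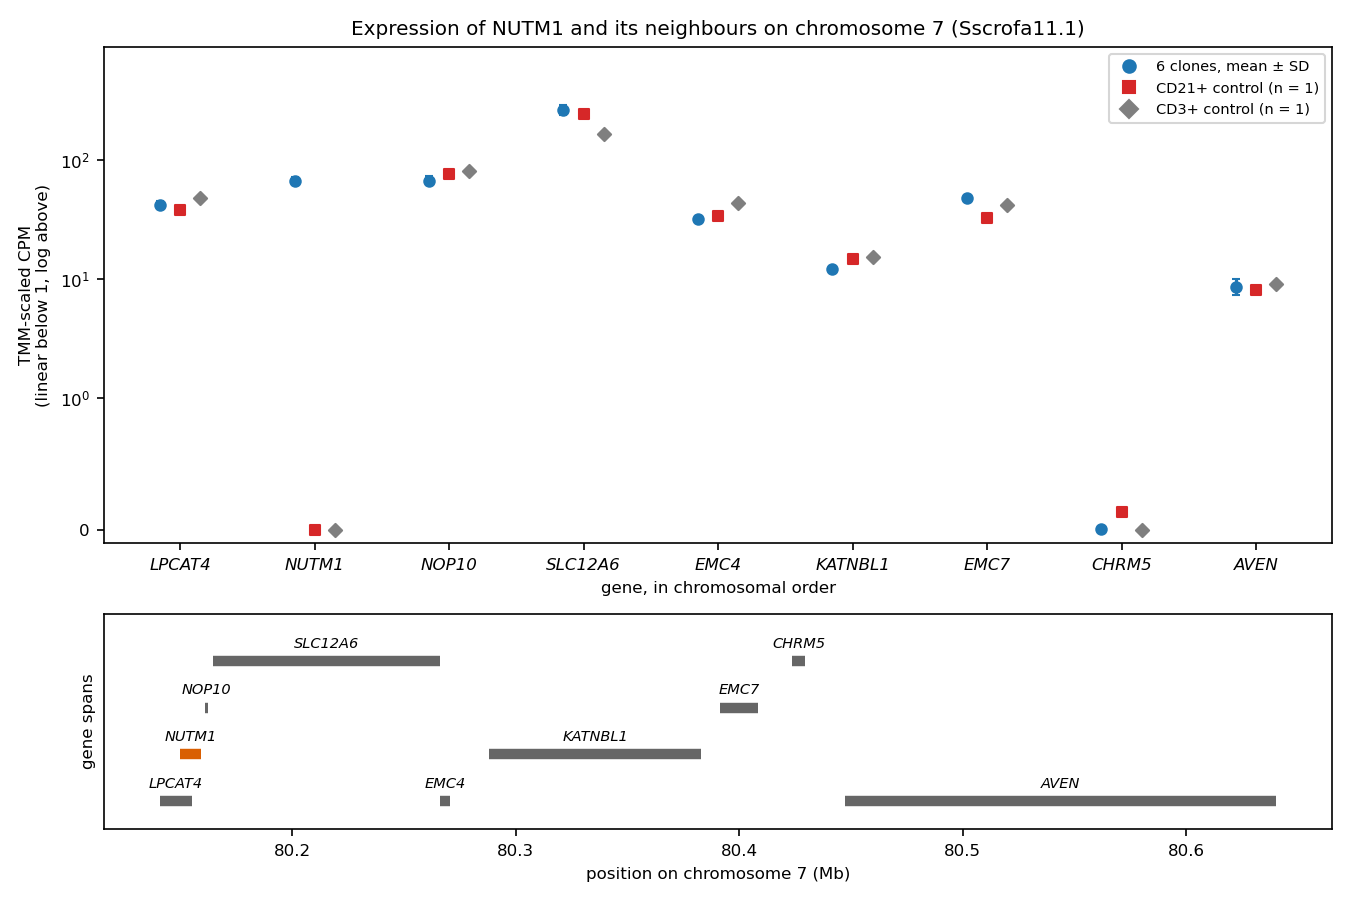
Levels in CPM (linear below 1, log above) of NUTM1 and its neighbours on chromosome 7, in chromosomal order, as the mean ± SD of the 6 clones and a marker for each control library, above a map of the gene spans. NUTM1 stands at 67.1 ± 5.17 CPM in the clones and at 0 in both controls, while LPCAT4, which it overlaps, stands at 42.1 ± 3.46, 38.5 and 48.0 CPM.

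KLF4, ANKRD33B, VXN, ADAM3A, BBOX1, F5, NUDT16, CD163, SERPINB2 and PLPP3 had the lowest fitted log2 fold changes of the eligible genes, an order that depends on the prior count too. ANKRD33B, VXN, ADAM3A, BBOX1, NUDT16, CD163 and SERPINB2 had 0 counts over the 6 clones. CD163, a scavenger receptor of macrophages, stood at 16.3 CPM in the CD21+ library and was at least 792-fold lower in the clones. F5, coagulation factor V, had 3 counts over the clones against 1961, a ratio of 4361 (95% counting interval 1489.9 to 21163). PLPP3, a lipid phosphatase, had 2 counts against 1225, a ratio of 4086 (1129 to 33777).

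B cell identity genes mostly fell. Of 22 tested members, 3 rose (PAX5, EBF1 and FCRLA) and 17 fell, and CD79B (log2 -0.39 ± 0.23, adjusted p = 0.168) and CD72 did not pass. CD79B passed without lymph node clone 4, at log2 -0.48 (adjusted p = 0.0430). EBF1 rose by 2.33 ± 0.23 and PAX5 by 0.92 ± 0.17 on the log2 scale. MS4A1, a surface protein of mature B cells, stood at 419 ± 56.6 CPM against 1338. CD79A, a B cell receptor chain, fell by 1.20 ± 0.12. TNFRSF13C, the BAFF receptor that sustains mature B cells, stood at 1.57 ± 1.60 against 291 CPM, with 4.74 in lymph node clone 1 and 0.293 to 1.44 in the others, and BANK1 at 16.5 ± 2.74 against 285. The camera test called the list lower (adjusted p = 0.000856), with adjusted p = 0.317 with an estimated correlation. B cell receptor signalling genes went the same way, with 3 of 22 higher (SYK, PIK3AP1 and NFATC1) and 17 lower, among them VAV2 at log2 -4.53 ± 0.42 (camera adjusted p = 0.000298, and adjusted p = 0.317 with an estimated correlation).

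Of 11 tested early B progenitor genes 9 rose, among them RAG2, DNTT, LEF1, ERG, IL7R and VPREB1, while KIT fell and RAG1 did not pass. VPREB1, part of the surrogate light chain of the pre-B cell receptor, stood at 596 ± 127 against 4.53 CPM, and IL7R at 86.9 ± 21.9 against 1.14. DNTT, the polymerase that adds bases at V(D)J joins, stood at 12.3 ± 6.06 CPM against 0 counts, at least 89.4-fold higher. RAG2, part of the V(D)J recombinase, had 15918 counts over the clones against 2, a ratio of 1193 (95% counting interval 330.2 to 9853), or 648 without lymph node clone 4. RAG1 stood at 6.64 ± 11.5 CPM against 0 counts (edgeR adjusted p = 0.108), and it passed without lymph node clone 4, at adjusted p = 0.00620. In lymph node clone 4 alone RAG1 and RAG2 stood at 29.9 and 319 CPM. KIT had 1 count against 23, a ratio of 153 (24.9 to 6320.4). The list's median log2 fold change was 7.57, or 6.48 with genes at 0 set to their bound (camera adjusted p = 0.0138, and adjusted p = 0.366 with an estimated correlation). Of the immunoglobulin list only 2 members were tested, VPREB1, which rose, and JCHAIN, which fell from 1599.8 to 17.2 ± 2.76 CPM.

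Germinal centre genes fell in 10 of 14 members and rose in BCL6, BACH2 and EZH2. RGS13, a regulator of G protein signalling, stood at 0.0701 ± 0.0419 against 14.2 CPM. BCL6, the repressor that drives the germinal centre programme, rose by 1.14 ± 0.30 on the log2 scale (adjusted p = 0.00919). Plasma cell genes fell in 11 of 16 members and rose in SDC1, CREB3L2 and SLAMF7. PRDM1 and IRF4, regulators of plasma cell fate, fell by 4.15 ± 0.34 and 0.62 ± 0.14, and TNFRSF17 stood at 0.0245 ± 0.0380 against 8.78 CPM. Camera called both lists lower (adjusted p = 0.00864 and 0.00492), with adjusted p = 0.304 and adjusted p = 0.317 with an estimated correlation.

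Markers of other cell types were mostly lower in the clones than in the CD21+ library. Of 19 T cell identity genes 12 fell, among them CD3E (log2 -5.47 ± 0.31), CD8A (-7.82 ± 0.29) and CD3G (-5.00 ± 0.50). CD4 had 2 counts against 26, a ratio of 86.7 (95% counting interval 21.7 to 754). CD5, CD96, ICOS and SKAP1 rose, SKAP1, a T cell adaptor protein, by 3.30 ± 0.12 to 74.7 ± 3.59 CPM, and CD247, LAT and TCF7 did not pass. Of 8 NK and cytotoxic genes 7 fell, with TBX21, a regulator of type 1 immunity, at 0.0744 ± 0.0518 against 72.7 CPM, and NKG7 rose. Myeloid genes fell in 16 of 21 members and rose in MPO and FCGR1A. Stroma and endothelium genes fell in 7 of 9 members, with FN1 at log2 -9.84 ± 0.44, and rose in PDGFRB. These 4 lists were called lower by camera (adjusted p = 0.0224, 0.00168, 1.09e-05 and 0.00272), with adjusted p = 0.317, 0.260, 0.274 and 0.317 with an estimated correlation. Of 5 erythroid and platelet genes 3 fell and ITGA2B rose by 0.59 ± 0.08, with a list median of -7.15, or -5.15 with genes at 0 set to their bound (camera adjusted p = 0.123).

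Proliferation genes rose in 29 of 32 tested members, while TYMS fell by 0.71 ± 0.09 on the log2 scale and CENPE and GINS2 did not pass. UHRF1, a maintenance factor of DNA methylation in dividing cells, stood at 375 ± 56.3 against 69.4 CPM, CDC20, an activator of mitotic exit, at 199 ± 23.8 against 51.9, and CENPF, a kinetochore protein, at 304 ± 47.9 against 85.9. Glycolysis and hypoxia genes rose in 19 of 24 members and fell in CA9 and EGLN3. VEGFA, the angiogenic growth factor, rose by 4.59 ± 0.31, and SLC16A3, a lactate exporter, by 4.76 ± 0.49. Cholesterol and lipid synthesis genes rose in 16 of 19 members and fell in 0. SQLE, an enzyme of sterol synthesis, rose by 2.30 ± 0.13. Camera called the 3 lists higher (adjusted p = 1.15e-07, 8.41e-05 and 5.03e-06), each with adjusted p = 0.317 with an estimated correlation. Amino acid stress genes rose in 11 of 21 members, among them PHGDH and PSAT1, enzymes of serine synthesis, at 155 ± 47.3 and 233 ± 149 against 4.89 and 2.97 CPM. In that list ATF4, DDIT3, CEBPB, ATF3 and HSPA5 fell, and the list was not called (camera adjusted p = 0.637).

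MHC class II genes fell in 9 of 11 members and rose in 0. CIITA, their master activator, stood at 208 ± 53.4 against 491 CPM, and SLA-DMB, a chain of the peptide-loading protein, at 79.4 ± 24.4 against 486, with reads of related SLA genes possible among them. MHC class I genes fell in 10 of 11 members, with B2M, the light chain, at 153 ± 14.2 against 709 CPM and NLRC5, an activator of class I genes, at 20.7 ± 1.51 against 470.1. Interferon response genes fell in 18 of 24 members, ISG15 at log2 -4.87 ± 0.31, and rose in IFIT2 and IFIT5. The 3 lists were called lower (camera adjusted p = 0.00664, 0.000155 and 0.000298), with adjusted p = 0.355, 0.317 and 0.317 with an estimated correlation. NF-kB genes fell in 18 of 22 members, NFKBIZ at log2 -4.85 ± 0.20, TNFAIP3, a brake on NF-kB, at log2 -2.14 ± 0.17 and CD40 at -0.71 ± 0.11, and rose in LTA. Immediate-early and stress genes fell in 19 of 25 members, with EGR1 at 20.1 ± 6.78 against 825 CPM and FOSB at 11.9 ± 5.61 against 626, and rose in IER3 and DNAJB1. Homing and adhesion genes fell in 16 of 20 members, ITGB2, the shared chain of leukocyte integrins, at log2 -8.80 ± 0.23, and rose in CCR10 and S1PR4. Camera called these 3 lists lower too (adjusted p = 9.91e-06, 8.44e-06 and 1.09e-05), with adjusted p = 0.317, 0.317 and 0.260 with an estimated correlation.

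Cytokine and receptor genes fell in 13 of 20 members, IL6R at log2 -6.08 ± 0.66, and rose in IL7R, IL18, TNFSF13B and CSF1 (camera adjusted p = 0.00411, and adjusted p = 0.317 with an estimated correlation). Costimulation and checkpoint genes fell in 9 of 18 members, CD274, which encodes PD-L1, at log2 -3.95 ± 0.43 and CD80 at log2 -4.09 ± 0.31, rose in 5, and were not called as a list (camera adjusted p = 0.316). CD86 did not pass, at 145 ± 29.2 against 152 CPM. Lymphoma oncogenes rose in 6 of 24 members and fell in 14 (camera adjusted p = 0.123). MYB, a transcription factor of blood progenitors, rose by 6.10 ± 0.24, while NOTCH2 fell by 5.11 ± 0.58 and MYC by 0.75 ± 0.14. MYC and ribosome biogenesis genes rose in 9 of 25 members, among them NOLC1 and CAD, and fell in 5, with a list median of 0.02 that turned to -0.01 under RLE size factors and in DESeq2 (camera adjusted p = 0.462). Of these genes 15 rose and 1 fell under total-count scaling. Apoptosis genes fell in 9 of 20 members, MCL1 at log2 -2.07 ± 0.14 and PMAIP1 at log2 -2.47 ± 0.13, and rose in 4, with a list median of -0.26 that turned to 0.04 under total-count scaling, where 9 fell and 8 rose (camera adjusted p = 0.123). Cell cycle inhibitor and p53 genes rose in 7 of 16 members and fell in 7, with a median of -0.01, a mean of 0.68 and a median of 0.29 under total-count scaling, where 8 rose and 4 fell (camera adjusted p = 0.913, higher). CDKN2C, an inhibitor of CDK4 and CDK6, rose by 2.41 ± 0.40 and CDKN1A by 3.99 ± 0.72, and BTG1 fell by 2.19 ± 0.22.

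Telomere genes rose in 2 of 8 members and fell in 3, but rose in 4 and fell in 0 under total-count scaling. The list median of 0.02 turned to -0.004 under RLE size factors and in DESeq2 (camera adjusted p = 0.841). POT1, a telomere-binding protein, rose by 0.97 ± 0.24, and TERT, the telomerase catalytic subunit, fell by 0.75 ± 0.19 but did not pass under total-count scaling (adjusted p = 0.0897). All 13 mitochondrially encoded genes fell (12 under total-count scaling), ND2 at log2 -1.33 ± 0.07, beside the mitochondrial share of counts of 7.07 ± 0.562% in the clones and 10.9% in the CD21+ library. Ribosomal protein genes fell in 58 of 73 members and rose in 4, with RPL37 at 858 ± 47.3 against 2041 CPM and pseudogene reads possible. Camera called both lists lower (adjusted p = 9.51e-05 and 1.84e-07), each with adjusted p = 0.317 with an estimated correlation. Of 29 lists tested, camera called 21, 4 higher and 17 lower, and none with an estimated correlation. Adjusted over the list alone, member counts equalled those over all genes tested except in 3 lists: 8 higher and 4 lower for MYC and ribosome biogenesis, 17 lower for myeloid, and 20 higher for glycolysis and hypoxia. With limma-voom, MEIS1, ICOS, DNTT, RAG2 and PSAT1 no longer passed.

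**Figure D3:**
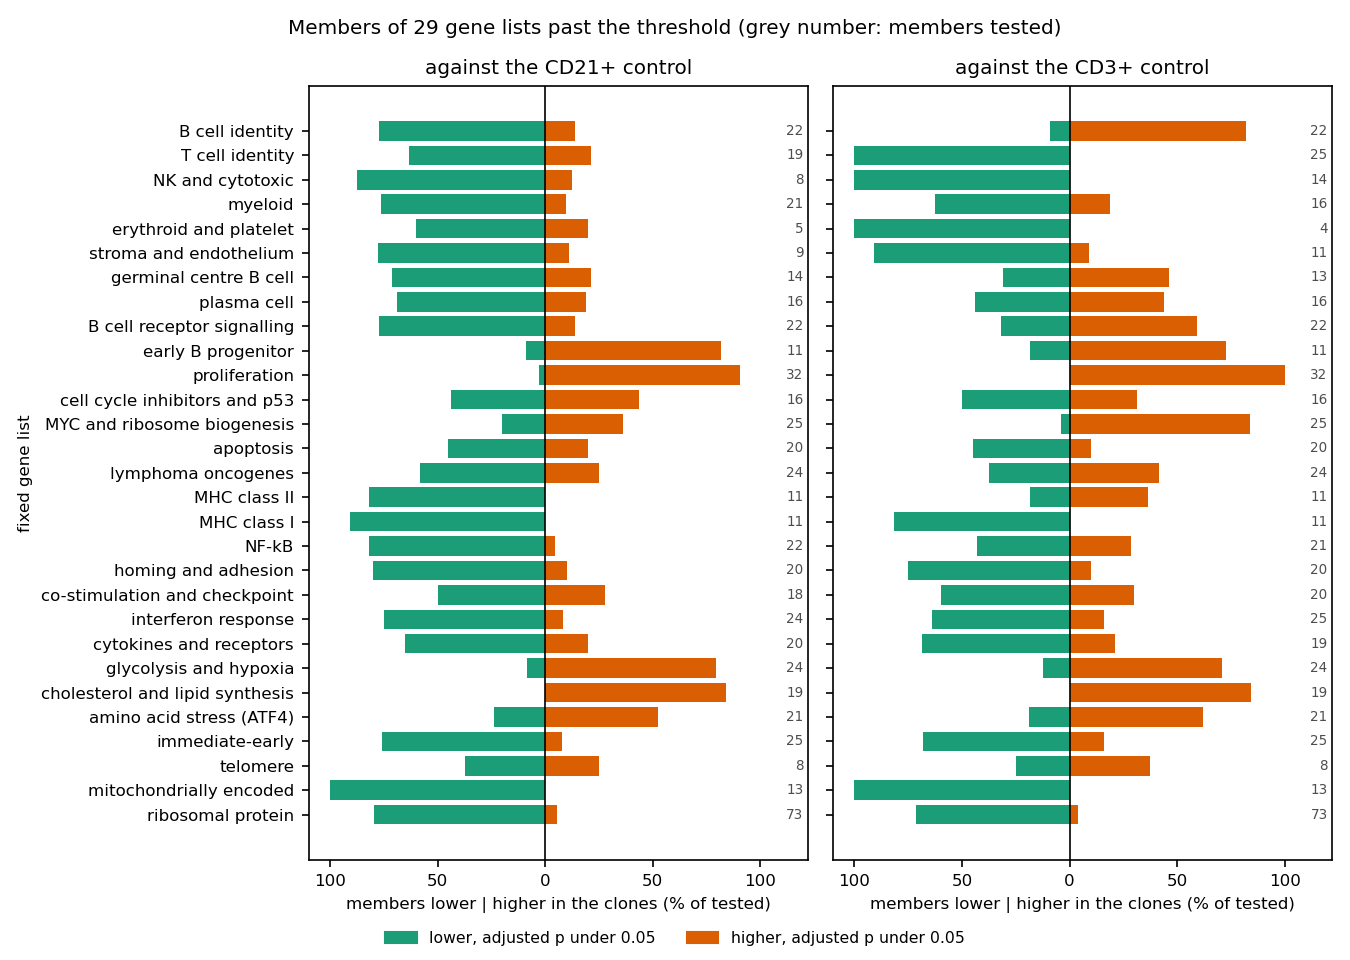
Percent of the tested members of each fixed gene list that were higher or lower in the 6 clones, drawn to the right and left of 0, against the CD21+ and the CD3+ library. Among B cell identity genes, 3 of 22 were higher and 17 lower against the CD21+ library, and 18 higher and 2 lower against the CD3+ library; under total-count scaling the medians of the apoptosis and cell cycle inhibitor lists change sign against both controls, as does that of NF-kB against the CD3+ library, and under RLE size factors and in DESeq2 those of the MYC and telomere lists against the CD21+ library.

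The comparison with CD3+ splenocytes addresses the same question from the T cell side. The T cell receptor component CD3D was lower in all 6 clones, at 0.0914 ± 0.0778 against 643 CPM. CD3E fell by 12.70 ± 0.15 and CD8A by 12.51 ± 0.12 on the log2 scale (edgeR adjusted p = 8.55e-10 and 1.93e-10). MS4A1 and CD79B rose by 5.60 ± 0.28 and 6.82 ± 0.41 (adjusted p = 9.61e-07 and 2.27e-06). NUTM1 also had 0 counts in the CD3+ library and was at least 373-fold higher in the clones. Of 13560 genes tested, 9757 passed, 4992 higher and 4765 lower in the clones, and 6021 of these differed 2-fold or more. Under total-count scaling the median log2 fold change of all genes moved from 0.05 to 0.51, and 6854 of 9968 genes passing were higher.

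RAG2, ELOVL2, TRHDE, NUTM1, DBX1, EMCN, DDAH1, CNNM1, KHDRBS3 and ADAM11 had the highest fitted log2 fold changes of the eligible genes, with bounds from at least 207-fold for ADAM11 to at least 563-fold for RAG2, or 322-fold for RAG2 without lymph node clone 4. All 10 had 0 counts in the CD3+ library, and their bounds do not rank them above genes such as EBF1. EMCN, an endothelial sialomucin also found on blood stem cells, stood at 48.1 ± 17.8 CPM. EPHB6, CRTAM, PRKCQ, HPSE, PSTPIP1, GZMB, CD244, PRF1 and CD3D were among the 10 with the lowest fitted values. PRF1, the pore-forming protein of cytotoxic cells, had 0 counts in the clones against 37.7 CPM, at least 1833-fold lower. GZMB, a protease of cytotoxic granules, had 1 count against 1492, a ratio of 13064 (95% counting interval 2341 to 516323). PRKCQ, a kinase of T cell receptor signalling, had 1 count against 2217, a ratio of 19411 (3480.4 to 767051).

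B cell identity genes rose in 18 of 22 members, fell in BLK and CD37, and did not pass in TNFRSF13C and CXCR5. PAX5 rose by 8.53 ± 0.29, EBF1 by 9.98 ± 0.43 and CD79A by 0.86 ± 0.15, the last from 115 CPM in the CD3+ library. BLK, a kinase of the B cell receptor pathway, stood at 10.9 ± 3.01 against 173 CPM, and CD37 fell by 0.67 ± 0.16 but did not pass under total-count scaling (adjusted p = 0.324). B cell receptor signalling genes rose in 13 of 22 members and fell in 7 (14 and 3 under total-count scaling), with BTK and BLNK, 2 signal relays of the receptor, up by 6.21 ± 0.17 and 6.28 ± 0.20. Camera called both lists higher (adjusted p = 0.000104 and 0.0331), with adjusted p = 0.372 and 0.600 with an estimated correlation. All 25 T cell identity genes and all 14 NK and cytotoxic genes fell, CD4 with 2 counts against 2098, a ratio of 9185 (95% counting interval 2539 to 75891), and EOMES at log2 -12.71 ± 0.16. Both lists were called lower (camera adjusted p = 4.16e-13 and 7.51e-09), with adjusted p = 0.0636 and 0.0848 with an estimated correlation.

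Myeloid genes fell in 10 of 16 members and rose in CSF1R, MPO and FCGR1A, with C1QB, a complement component made by macrophages, at 2 counts against 643, a ratio of 2815 (95% counting interval 776 to 23294). Stroma and endothelium genes fell in 10 of 11 members, FN1 at log2 -6.54 ± 0.70, and rose in PDGFRB. All 4 erythroid and platelet genes fell, HBB at 0 counts against 8.23 CPM, with a list median of -5.12, or -4.14 with genes at 0 set to their bound, but ITGA2B, at log2 -0.19, passed as higher under total-count scaling (0.26, adjusted p = 0.0109). Camera called these 3 lists lower (adjusted p = 0.0145, 0.000566 and 0.0216), each with adjusted p = 0.372 with an estimated correlation. Early B progenitor genes rose in 8 of 11 members, ERG by 9.57 ± 0.39, and fell in IL7R (log2 -1.48 ± 0.26) and in KIT, with 1 count against 793, a ratio of 6943 (1243 to 274586). The list median was 6.04, or 5.21 with genes at 0 set to their bound, and the list was not called (camera adjusted p = 0.162). RAG1 stood at 0 counts in the CD3+ library and did not pass (edgeR adjusted p = 0.121), but passed without lymph node clone 4, at adjusted p = 0.00864. Of the immunoglobulin list, VPREB1 rose and JCHAIN fell.

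Germinal centre genes rose in 6 of 13 members, LMO2 by 5.30 ± 0.25, and fell in 4, with a median of 0.30 and a mean of -0.09 (camera adjusted p = 0.593, higher). BCL6 rose by 0.77 ± 0.29 (edgeR adjusted p = 0.0402), and did not pass without lymph node clone 2, lymph node clone 3 or spleen clone 1 (adjusted p = 0.0628, 0.0637 and 0.0642). Plasma cell genes rose in 7 of 16 members and fell in 7 (9 and 6 under total-count scaling), with a median of 0.07 and a mean of -0.25 (camera adjusted p = 0.990, higher). IRF4 rose by 3.39 ± 0.19, CREB3L2 by 4.37 ± 0.44, and PRDM1 fell by 5.69 ± 0.29. Lymphoma oncogenes rose in 10 of 24 members, among them MYB by 4.61 ± 0.21 and MYC by 0.71 ± 0.16, and fell in 9 (camera adjusted p = 0.751). Cell cycle inhibitor and p53 genes rose in 5 of 16 members, CDKN2C by 2.81 ± 0.42, and fell in 8, with a list median of -0.14 that turned to 0.31 under total-count scaling, where 7 rose and 5 fell (camera adjusted p = 0.593). Apoptosis genes fell in 9 of 20 members, PMAIP1 at log2 -3.30 ± 0.12, and rose in 2, with a list median of -0.07 that turned to 0.38 under total-count scaling, where 9 rose and 6 fell (camera adjusted p = 0.25). Telomere genes rose in 3 of 8 members, DKC1 by 1.29 ± 0.10, and fell in 2, against 5 and 1 under total-count scaling (camera adjusted p = 0.593).

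All 32 proliferation genes rose, UHRF1 by 3.46 ± 0.26 and CDC20 by 3.40 ± 0.22. MYC and ribosome biogenesis genes rose in 21 of 25 members, NOLC1, a nucleolar protein, and HSPD1, a mitochondrial chaperonin, each by 1.63 ± 0.10, and fell in BOP1, which at log2 -0.21 turned to 0.25 under total-count scaling (adjusted p = 0.0409). Glycolysis and hypoxia genes rose in 17 of 24 members, HK2, the first enzyme of glycolysis, by 6.26 ± 0.46 and VEGFA by 4.68 ± 0.32, and fell in PFKP, CA9 and PDK1, with PFKP turning from log2 -0.34 to 0.12 under total-count scaling, where it did not pass. Cholesterol and lipid synthesis genes rose in 16 of 19 members, SQLE by 4.30 ± 0.15 and SCD, a fatty acid desaturase, by 3.45 ± 0.22, and fell in 0. Camera called the 4 lists higher (adjusted p = 1.37e-11, 3.37e-06, 0.000914 and 3.11e-06), with adjusted p = 0.372, 0.372, 0.504 and 0.372 with an estimated correlation. Amino acid stress genes rose in 13 of 21 members, PHGDH by 4.22 ± 0.55 and PSAT1 by 6.35 ± 1.39, and fell in ATF4, DDIT3, DDIT4 and CEBPB (camera adjusted p = 0.344).

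MHC class II genes rose in 4 of 11 members, CIITA by 2.64 ± 0.44, and fell in 2, against 6 and 0 under total-count scaling (camera adjusted p = 0.505). NF-kB genes rose in 6 of 21 members, CD40 by 6.51 ± 0.21, and fell in 9, NFKBIZ at log2 -4.37 ± 0.20, with a list median of -0.22 that turned to 0.24 under total-count scaling, where 9 rose and 8 fell (camera adjusted p = 0.402). Costimulation and checkpoint genes rose in 6 of 20 members, CD86 by 1.54 ± 0.29, and fell in 12, LAG3 at log2 -6.94 ± 0.28 and CD274 at log2 -2.79 ± 0.49 (camera adjusted p = 0.125). MHC class I genes fell in 9 of 11 members, B2M at log2 -2.76 ± 0.11 and NLRC5 at log2 -4.18 ± 0.08. Homing and adhesion genes fell in 15 of 20 members, ITGB2 at log2 -9.54 ± 0.23 and S1PR1 at log2 -8.57 ± 0.25, and rose in CCR6 and CCR10. Camera called both lists lower (adjusted p = 0.000985 and 6.15e-05), with adjusted p = 0.431 and 0.206 with an estimated correlation. Interferon response genes fell in 16 of 25 members, DDX60 at log2 -5.38 ± 0.34 and ISG15 at log2 -4.14 ± 0.34, and rose in 4. Cytokine and receptor genes fell in 13 of 19 members, IL2RB at log2 -9.17 ± 0.22 and IL6R at log2 -9.73 ± 0.36, and rose in 4. Immediate-early and stress genes fell in 17 of 25 members, JUNB at log2 -4.77 ± 0.22, and rose in IER3, HSPA8, DNAJB1 and HSPH1. These 3 lists were called lower (camera adjusted p = 0.00258, 0.00961 and 0.000570), with adjusted p = 0.404, 0.395 and 0.372 with an estimated correlation.

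All 13 mitochondrially encoded genes fell against the CD3+ library, ND2 at log2 -2.57 ± 0.07, beside mitochondrial shares of counts of 7.07 ± 0.562% in the clones and 21.6% in the CD3+ library. Ribosomal protein genes fell in 52 of 73 members, RPL37 at log2 -1.15 ± 0.09, and rose in 3; under total-count scaling 31 fell and 14 rose. Camera called both lists lower (adjusted p = 1.04e-06 and 3.43e-06), with adjusted p = 0.372 and 0.497 with an estimated correlation. Of 29 lists tested, camera called 18, 6 higher and 12 lower, and none with an estimated correlation. Adjusted over the list alone, member counts equalled those over all genes tested except in 5 lists: 5 lower for germinal centre, 14 higher for B cell receptor signalling, 8 lower for apoptosis, 17 lower for interferon response, and 5 higher for cytokines and receptors. With limma-voom, RAG2, EMCN, PSAT1 and BCL6 no longer passed.

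Lymph node and spleen clones were set against each other because the labels give these as the 2 tumour sites; the study description names no question for this comparison. Of 21 amino acid stress genes 0 passed. PSAT1 stood at 289 ± 155 CPM (n = 4) in the lymph node clones against 120.1 (n = 2) in the spleen clones, but at 104 in lymph node clone 4 against 146 in spleen clone 2, and CHAC1, a glutathione-degrading enzyme induced by that stress, at 33.7 ± 20.8 against 11. Among B cell identity genes, BLK stood at 12.6 ± 1.92 against 7.56 CPM and BANK1 at 17.8 ± 2.25 against 13.8. INSIG1, a sensor of sterol synthesis, stood at 56.2 ± 4.80 against 80.0 CPM, and COX1, encoded by the mitochondrial genome, at 21011 ± 2770.1 against 25324. No gene passed in edgeR, where 605 of 12580 had an unadjusted p under 0.05; limma-voom called 0 and DESeq2 called 20 (11 higher and 9 lower in lymph node clones). PSAT1, CHAC1, BLK, BANK1, INSIG1 and COX1 each had edgeR adjusted p = 0.942, and INSIG1 passed in DESeq2 (adjusted p = 0.0121). Without lymph node clone 4 edgeR called 1 gene. With the replicate number as a block it called 570, among them PSAT1, CHAC1, BLK, INSIG1 and COX1. The labels do not say that the numbers pair the clones, and that fit compares only the clones numbered 1 and 2. The lymph node clones whose number no spleen clone shares are fitted exactly there. A gene's own spread thus rests on a single contrast, between numbers 1 and 2, so the 570 calls are not read as a site effect.

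Camera called 4 of 28 lists between sites: amino acid stress (median log2 0.45, adjusted p = 1.25e-05) and B cell identity (0.18, adjusted p = 0.00210) higher in lymph node clones, and cholesterol and lipid synthesis (-0.07, adjusted p = 0.00865) and mitochondrially encoded genes (-0.08, adjusted p = 0.0173) lower. Each had adjusted p = 0.991 with an estimated correlation, and fry called 0 lists. The other 24 had camera adjusted p from 0.0672, for homing and adhesion, to 0.963. On leaving out a single clone the calls of B cell identity, cholesterol and lipid synthesis and mitochondrially encoded genes were each lost in some fit (highest camera adjusted p = 0.836, 0.102 and 0.227), while camera called 16 lists without spleen clone 1 and 8 without lymph node clone 4. In none of the 28 lists did a member pass over all genes tested; adjusted over the list alone, 1 homing and adhesion gene was higher and 1 cholesterol and lipid synthesis gene lower. Median, mean and test differed in sign in the plasma cell, MYC, apoptosis, MHC class II, MHC class I, NF-kB and costimulation lists, with medians from -0.03 to 0.15. Of the fixed set of B cell, T cell and lymphoma genes, 15 were tested, with log2 fold changes from -0.81 for CD274 to 0.74 for CD3E and adjusted p of 0.942 or more.

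The authors' deposited table compares the CD21+ library with the 6 clones and gives 8412 of 22366 features a false discovery rate under 0.05, 4233 higher and 4179 lower in the clones. Of these, 8046 were among the 13498 genes tested here, and 7933 also passed in the refit, all in the same direction. Of the 1136 genes that passed only in the refit, 92.4% differed less than 2-fold, and 113 passed only in the authors' deposited table. The median difference in log2 fold change, the authors' deposited table minus the refit, was 0.01. The authors' second deposited comparison sets the CD21+ library against the 6 clones and the CD3+ library together, and there 766 features passed, 354 higher and 412 lower outside the CD21+ library.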

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

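All tests of an explanation in this part were chosen after the result was seen. A library stood apart where its gap to the nearest other clone was large for the range of the group (Dixon's ratio at the 95% level). Of 148 groups of clones examined 20 stood out, 7 of them genes under 1 CPM in every clone, where a stray count fixes the ratio. Without genes of that kind 13 of 124 groups stood out, where chance gives about 1 in 20, or 6.2, for independent normal values. Lymph node clone 4 was the library apart in 12 of them. Of 119 genes tested for a difference between sites in edgeR, 0 passed the adjusted threshold.

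Lymph node clone 4 held RAG1 at 29.9 CPM (1.21 to 4.23 in the other clones), RAG2 at 319 (35.6 to 96.5), DNTT at 24.4 (7.61 to 11), ICOS at 32.3 (10.9 to 15), LEF1 at 1708 (1135 to 1273), IL7R at 129 (65.8 to 86.6), ERG at 236 (166 to 190.3) and MMP14 at 877 (627 to 685). It held VAV2 at 4.96 CPM (15.5 to 20.3 in the other clones), CDKN2C at 110.1 (205 to 232) and CNNM1 at 24.8 (44.0 to 48.7). Among the 4 lymph node clones it also held INSIG1 at 49.1 CPM (57.6 to 59.2). TNFRSF13C stood at 4.74 CPM in lymph node clone 1 and at 0.293 to 1.44 in the others.

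In 7 genes under 1 CPM in every clone, a lone library held counts and the others none. These were PLPP3 and C1QB at 0.0758 CPM in lymph node clone 3, PRKCQ and GZMB at 0.0379 in the same clone, KIT and PSTPIP1 at 0.0475 in lymph node clone 2, and EPHB6 at 0.0419 in spleen clone 2.

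Spleen clone 2 stood nearest to lymph node clone 4 in the genes that set the latter apart. These were 15 genes at least 4-fold higher there than in the other 4 clones, among them SLC6A4, RAG2, HNRNPLL and CADM1. Over them spleen clone 2 lay a median 16.3% of the way toward lymph node clone 4 (95% interval 13.1 to 20.1). Intervals of these shares come from resampling the genes, which may vary together, and do not measure spread between libraries. Reads misassigned alike among all libraries are argued against, since the highest median in the other 4 clones was 2.33%, with upper limits of at most 5.21%. Cells or RNA of the lymph node clone 4 kind in spleen clone 2 may account for these 15 genes. A mixture would bring a similar share to each gene, but single shares ran from 7.22% to 28.1%. That spread was not tested against counting error or variation between clones. A mixture would also shift the 21 genes that lymph node clone 4 had lost by the same share. That shift was 10.1% (1.80 to 33.1), but another clone's median reached 13.9%. Such a mixture and a shared ancestry of both clones therefore cannot be told apart. HOXA9 stood at 5.95 CPM in spleen clone 2 and 4.96 in lymph node clone 4, and a mixture at that upper limit of 20.1% would bring 1.64, so it would not account for HOXA9. No biological explanation was tested, since the labels do not say how the clones are related.

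Of immediate-early, homing and NF-kB genes 19 of 25, 16 of 20 and 18 of 22 were lower in the clones than in the CD21+ library, while IER3, DNAJB1, CCR10, S1PR4 and LTA rose (list adjusted p = 0.317, 0.260 and 0.317 with an estimated correlation). T cells in the CD21+ library are argued against: at the share that CD8A allows, 3.89% of the CD3+ level, they would supply a median 5.32% of the gap over 52 lower genes (quartiles 1.98 to 9.11), and 50% or more for 0 genes. Myeloid cells in that library were not tested as a source, though 16 myeloid genes were lower in the clones and 2 higher. C1QC stood at 58.7 CPM in the CD21+ library against 0.0228 in the clones, and CD163 at 16.3 against 0. As to scaling, the choice between TMM and total-count scaling is argued against. It moved the median log2 fold change of all genes from 0.05 to 0.35, too little to account for these lists. The highest of the 3 list medians was -1.31 on the log2 scale under total-count scaling. Handling of the freshly isolated splenocytes could have raised such genes in both controls, and 17 of 25 immediate-early genes were also lower than in the CD3+ library. That cannot be told apart from culture of the clones or from the lymphoma itself, because every clone was cultured and no control was.

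Of 11 early B progenitor genes 9 passed as higher than in the CD21+ library, each in all 6 clones, while KIT fell (list camera adjusted p = 0.366 with an estimated correlation). RAG1 was also higher in all 6 clones, at 1.21 to 29.9 CPM, but did not pass. T cells of the kind in the CD3+ library are argued against as a part of the clones. T cell identity genes stood at a median 0.0241% of their CD3+ level (75th percentile 1.76%). The 3 progenitor genes that rose and reached 10 CPM there stood at 36.0% (IL7R), 355% (LEF1) and 385% (SOX4). Immature cells of the T lineage were not tested, since no library here holds them as a reference. The most abundant T cell gene, CD3E, stood at 0.0155% of its CD3+ level, and the clones had been through limiting dilution. The choice between TMM and total-count scaling is argued against, since it moved the median log2 fold change of all genes only from 0.05 to 0.35. The smallest log2 fold change of the members that rose was 5.05 under total-count scaling. Culture of the clones, which no control shared, was not tested as a cause, and neither was the hypothesis that the lymphoma may hold an early B cell programme, which was found on the same data.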

How the results depend on the processing

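Of the list members and named genes that passed, 4 of 476 against the CD21+ library and 15 of 479 against the CD3+ library changed sign under total-count scaling, ITGA2B and BOP1 with a call, and 0 in any other alternative. No similarity measure changed direction. List medians that changed sign against a control are given with their lists. Between sites those of the immunoglobulin and ribosomal protein lists changed sign, at 0.00 to 2 decimals before and after. Total-count scaling and the fits without lymph node clone 4 and spleen clone 2 were chosen after the data were seen. Against the CD21+ library 7558 to 9568 genes passed over all alternatives but the 2-fold limit, with 8589 to 9568 on leaving out each clone, and against the CD3+ library 8234 to 10222, with 9273 to 10222. The 2-fold limit gave 5298 and 6021, by its own construction. Under total-count scaling 66.7% and 68.8% of genes passing were higher, in place of 51.8% and 51.2%. Between sites edgeR called 0 genes (605 at an unadjusted p under 0.05), limma-voom 0 (606), DESeq2 20 (631) and the fit with a replicate block 570 (420 higher and 150 lower in lymph node clones, 2174 at p under 0.05). By its construction the block fit compares only the clones numbered 1 and 2. Numbers 3 and 4 occur among lymph node clones alone, so lymph node clone 4 does not enter its site difference. Both of those clones are fitted exactly, and a gene's own spread rests on a single contrast between numbers 1 and 2. Calls gained in the block fit are therefore weak support for a site difference. Whether shared numbers pair the clones was not decided: deviations from the site means correlated at 0.24 for number 1 and -0.05 for number 2, but those of 2 spleen clones mirror each other. Leaving out each clone gave 0 to 1 genes, the 1 without lymph node clone 4 (1843 at p under 0.05), and each of the 15 splits of the clones into 4 and 2 gave 0. Lists called by camera numbered 21 against the CD21+ library and 18 against the CD3+ library on leaving out each clone, and 3 to 16 between sites, 8 without lymph node clone 4 and 16 without spleen clone 1. An estimated correlation gave 0 in all 3 comparisons, and fry gave 25, 25 and 0. T cell identity genes lower than in the CD21+ library numbered 5 under the 5 CPM filter, where 12 of the members were tested in place of 19. Leaving out each clone gave similarity differences of 0.0623 to 0.0640 and positions of 0.196 to 0.202, with exact permutation p = 0.0625, the smallest that 5 clones allow. Pseudocounts cannot move a rank correlation, and gave positions of 0.176 to 0.229. Of 113 genes followed singly against the CD21+ library, 102 kept their direction and call in every alternative that tested them, 8 lost a call somewhere (MEIS1, ICOS, DNTT, RAG2, PSAT1, HOXA2 and HOXA3 by limma-voom, TERT under total-count scaling) and 2 gained one (CD79B and RAG1). The other, CD86, at log2 -0.08 without a call, changed sign without one in 3 alternatives (0.02 to 0.23). Of 77 against the CD3+ library, 71 kept both, 5 lost a call and 1 gained one. Between sites 2 of 10 kept both and 7 gained a call (PSAT1, CHAC1, TRIB3, ATF5, BLK, INSIG1 and COX1 with the replicate block, INSIG1 also in DESeq2). The other, RAG1, at 1.62 without a call, stood at -0.05 to -1.0 without one with a replicate block and in both fits without lymph node clone 4. Except where the construction is named, the cause was not tested. Depth limits genes with few counts: on the scaled levels a count of 0 allows up to 0.137 CPM in the CD21+ library and 0.180 in the CD3+ library.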

Other observations

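All tests in this part, and the genes it names, were chosen after the result was seen. Homeobox genes of the HOXA cluster on chromosome 18 were on in the clones. Besides HOXA7, HOXA3 stood at 26.5 ± 11.4 CPM (SD, n = 6), HOXA4 at 4.48 ± 1.57 and HOXA2 at 3.93 ± 1.84, with 0 counts in both controls, and HOXA5 at 10.8 ± 2.08 with at most 7 counts in a control. HOXA3, HOXA4, HOXA2 and HOXA5 passed against the CD21+ library (edgeR adjusted p = 0.00105, 0.000456, 0.00400 and 2.62e-05), and HOXA3 and HOXA2 did not pass with limma-voom (adjusted p = 0.173 and 0.0920). The span of HOXA3 holds those of HOXA4 and HOXA5, so reads may be shared among them in part. The activity was not limited to HOXA genes. HOXB7 stood at 21.3 ± 1.17 CPM against 0 in both controls, HOXB3 at 7.23 ± 0.627 and HOXB4 at 3.24 ± 0.653, each at 0.120 or less in both controls. HOXB5 and HOXB6 stood at 0.433 and 0.584 CPM, and HOXB1, HOXB2, HOXB8, HOXB9 and HOXB13 at 0.0694 or less. BMI1, a Polycomb repressor on chromosome 10, stood at 886 ± 199 against 68.2 CPM in the CD21+ library and 54.4 in the CD3+ library, a log2 fold change of 3.69 against the former (adjusted p = 5.18e-05). Its neighbour COMMD3 rose by 1.40 (adjusted p = 0.00264).

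MMP14, a membrane-anchored protease that cuts the extracellular matrix, stood at 689 ± 94.1 against 4.12 CPM in the CD21+ library (adjusted p = 4.67e-07). ITGA6, a laminin receptor chain, stood at 1319 ± 129 against 22.7 CPM (adjusted p = 2.98e-07). KCNJ2, a potassium channel subunit that neighbours KCNJ16 in other mammals, stood at 66.8 ± 4.00 against 0.274 CPM (adjusted p = 9.03e-08).

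NUTM1 was on in 6 of 6 clones with 0 counts in both controls. Reads of the overlapping gene LPCAT4 are argued against: the controls held 1641 LPCAT4 counts and 0 NUTM1 counts, at most 0.183 NUTM1 counts per 100 LPCAT4 counts, while the clones held 159.6. Activation of the whole neighbourhood is argued against too, since 7 tested genes within 500000 bp had a median log2 fold change of 0.10 (-0.29 to 0.56), with EMC7 the only 1 to pass (adjusted p = 0.000887). A change that acts on NUTM1 alone, such as a rearrangement of the kind known from human tumours, is a candidate explanation. Reads across junctions, which would test it, were not analysed here.

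Whether the whole HOXA cluster was active was tested as a hypothesis. Activation of the whole HOXA cluster is argued against, since 3 of 10 HOXA genes in the table, HOXA10, HOXA11 and HOXA13, stood under 2 CPM in the clones, at 0.00579 or less. The activity may thus be limited to part of the cluster, and HOXA9, at 2.35 ± 2.43 CPM, did not pass against the CD21+ library (edgeR adjusted p = 0.131). Its mean rested on lymph node clone 4 and spleen clone 2, at 4.96 and 5.95 CPM against 0.487 to 0.951 in the other 4, and without either of them 4 of the 10 genes stood under 2 CPM.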
